A study of Homo sapiens with 6 samples.

How the data were processed

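RNA from 6 A549 cultures, 3 with a UXS1 guide and 3 with a non-targeting guide, was sequenced, and groups and replicate numbers were taken from the sample titles. The submitters' processing notes name STAR, featureCounts, DESeq2 and the hg38 build without versions. The strand setting, the annotation release and the selection of messenger RNA are not given in the sources used here. The deposited table of counts holds whole-number counts per gene, per the file headers, with no normalization. The authors also deposited TPM values, which sum to 1000000 in each library. Over 25759 genes compared, the ratio of count to TPM gave 1 fixed length per gene within 0.01%. Counts were the basis of the main tests and TPM of an alternative.

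Of 28317 genes, 1406 had no count in any library. Genes were kept with edgeR's filterByExpr at its defaults (minimum count 10), which left 15757, and libraries were scaled with TMM factors between 0.987 and 1.01. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with group as the only term, two-sided, with Benjamini-Hochberg adjusted p under 0.05. A log2 fold change is UXS1 KO minus control. CPM values use the same factors. Counts at least 2-fold apart had an absolute log2 fold change of at least 1. The common dispersion was 0.0011, a biological coefficient of variation of 3.32%, and 1 CPM stands for 21.1 to 22.2 counts per library before scaling.

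The 43 gene lists were written from general knowledge before the data were examined, and none was chosen on these samples. Of 1342 list entries 1297 matched by symbol, 2 through a current symbol and 43 not at all. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Of single genes the text names UXS1 and UGDH, the 10 largest rises and the 10 largest falls past the threshold with at least 5 CPM in the higher group and no overlap between groups (clone identifiers left out), and up to 4 members of each list with the smallest adjusted p; IFI44L, CORO1A, IL6ST and OSMR in the report, CTPS1 and the members of added lists in the closing section were chosen after their values were seen. Some genes that the rule names are not reported here. Positions and exon overlaps come from GENCODE 29 on GRCh38, the assembly that hg38 names, and gene identifiers are those of the deposited table.

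The pipeline was tested on simulated data with the means, library sizes and common dispersion of this comparison, over 15758 genes with 200 changed. edgeR recovered 68% of 1.25-fold, 66% of 1.5-fold, 96% of 2-fold and 100% of 4-fold changes, with 9 false calls among 174. camera recovered 10 of 10 changed lists and called 1 of 30 unchanged lists. Simulated genes were drawn independently, so this cannot show how often camera makes false calls in lists of correlated genes. In the data the estimated correlation of cytosolic ribosomal protein genes was 0.680. Libraries of 1 group differed by more than sampling noise (chi-square per degree of freedom from 1.60 to 3.39, over genes with at least 20 counts in the pair), and libraries of different groups by 26.2 to 28.8, so no library was counted as a copy.

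Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, library size only, no filter, a mean of at least 5 CPM, robust dispersion, the replicate block, each library left out, and limma-trend on log2(TPM + 1) and log2(TPM + 0.1) with a mean TPM of at least 1 or no filter. For lists they were camera with an estimated correlation, fry, the replicate block, RLE scaling, the CPM minimum, TPM and each library left out. With an estimated correlation camera also takes its degrees of freedom from the few libraries, not from the many genes. Its adjusted p can thus rise without a higher correlation: for p53 targets the estimate was -0.0069, under the preset 0.01. A correction for GC content and transcript length, available for 99.4% of tested genes, was added after the data were seen.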

Results

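Messenger RNA levels were measured by RNA sequencing in A549, an established human lung adenocarcinoma cell line. Cells received lentiviral Cas9 with either a guide against UXS1 or a non-targeting control guide, were kept in puromycin for 5 days and were collected on day 7 after infection. UXS1 is the enzyme that makes UDP-xylose from UDP-glucuronic acid, and UGDH is the enzyme that makes UDP-glucuronic acid. Each group held 3 libraries, described in the series design as biological triplicates. No label says whether these were separate infections, so p values measure the spread among these cultures only. Total counts ran from 21121489 to 22160405 per library over 28317 genes. The comparison asks which transcripts differ between cells given the UXS1 guide (UXS1 KO below) and control cells.

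UXS1 transcript was lower in each library with the UXS1 guide. UXS1 (ENSG00000115652.14, GRCh38 chromosome 2, positions 106093303 to 106194339, minus strand, protein-coding) had 740, 735 and 764 counts in the UXS1 KO libraries and 1346, 1416 and 1372 in the control libraries. Its level was 34.6 ± 0.374 CPM in UXS1 KO and 63.9 ± 2.33 CPM in control (mean ± SD, n = 3 each), which is 54.1% of control. The log2 fold change was -0.89 (SE 0.048, edgeR adjusted p = 2.2e-14), and an exact two-sided permutation test of the CPM gave p = 0.1, the smallest value that 3 against 3 libraries allow. UGDH (ENSG00000109814.12, chromosome 4, positions 39498755 to 39528311, minus strand) stood at 653 ± 23.1 CPM against 614 ± 15.8 CPM, a log2 difference of 0.09 (SE 0.036, edgeR adjusted p = 0.047). The UGDH call was lost with DESeq2 (adjusted p = 0.0599), RLE scaling (0.0514), no filter (0.0560) and TPM, and it was lost without UXS1_KO replicate 1 (edgeR adjusted p = 0.277), UXS1_KO replicate 2 (0.0910), CTRL replicate 2 (0.125) or CTRL replicate 3 (0.0852). Over the alternatives its adjusted p ran from 0.0114 to 0.277, and UGDH overlaps an antisense gene on the opposite strand.

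In UXS1 KO cells most tested members of the cell division lists fell, while most members of the list of acute-phase, complement and cytokine receptor genes and of the interferon-stimulated and p53 target lists rose. With an estimated correlation the G2/M and p53 lists stayed called (adjusted p = 0.046 each), and the calls of the G1/S (adjusted p = 0.057), acute-phase, complement and cytokine receptor (adjusted p = 0.057) and interferon-stimulated lists (adjusted p = 0.13) were lost. Of 56 G2/M and mitosis genes 55 fell, with a median log2 fold change of -0.70, and of 52 G1/S and DNA replication genes 51 fell, with a median of -0.61. Of 18 tested acute-phase, complement and cytokine receptor genes 17 rose, with a median of 1.77. Of 40 p53 target genes 35 rose, with a median of 0.32. Of 15757 genes tested, 3863 were higher and 3727 lower in UXS1 KO at an adjusted p under 0.05 (edgeR quasi-likelihood test). Most of these changes were small: 5748 of the 7590 were under 1.5-fold. Changes of at least 2-fold went mainly up, with 592 genes higher and 84 lower. Among genes with a mean of at least 5 CPM these numbers were 157 and 12.

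**Figure D1:**
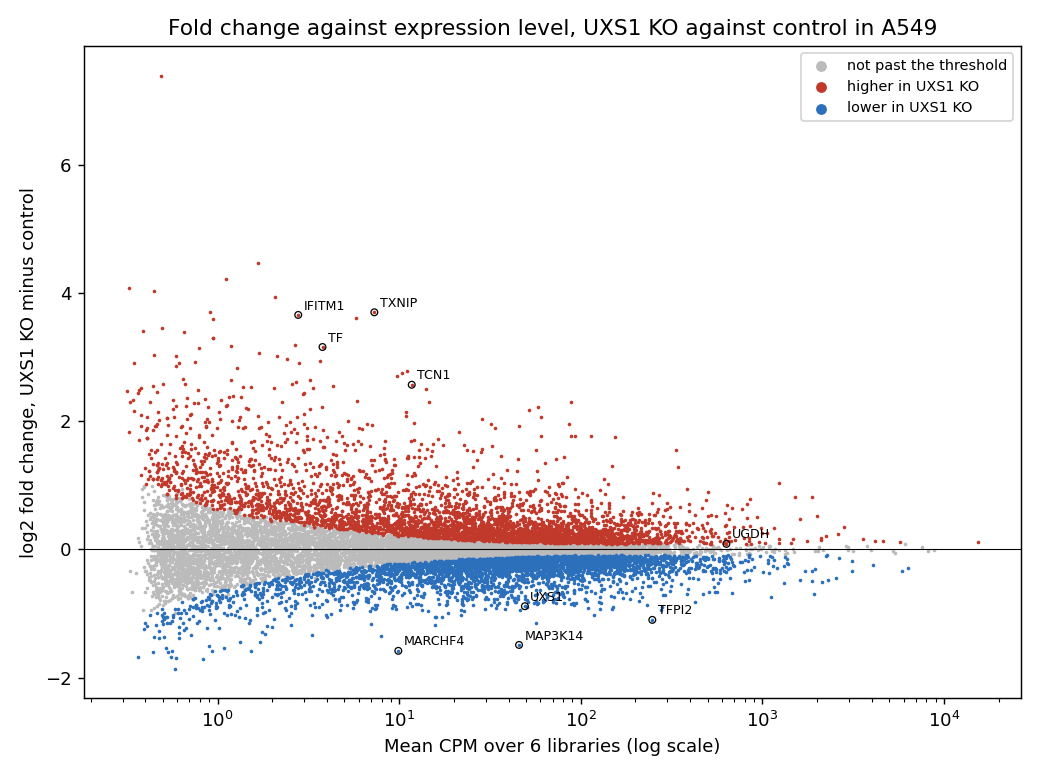
Each point is 1 of the 15757 genes tested, with its mean CPM over the 6 libraries on a log scale (x axis) and its log2 fold change, UXS1 KO minus control (y axis); red and blue points passed the edgeR threshold. The circled points are some of the genes named in the text, from TXNIP at 3.70 to MARCHF4 at -1.58; the uppermost point is IFI44L, which had no counts in the control libraries, so its height is not a measured fold.

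The steepest rise among the genes named by rule was that of TXNIP, a thioredoxin-binding protein whose transcript responds to glucose. It went from 1.03 ± 0.261 CPM to 13.6 ± 0.939 CPM (n = 3 each), a log2 fold change of 3.70 (SE 0.145, edgeR adjusted p = 3.8e-17). IFITM1, an interferon-induced membrane protein, rose by 3.66 (SE 0.24), and 32.5% of its exonic length overlaps IFITM2 on the same strand, so its value is uncertain. LBP, which binds lipopolysaccharide in plasma, rose by 3.62 (SE 0.161), from 0.862 to 10.7 CPM. The plasma iron carrier TF rose by 3.16 (SE 0.195) and SERPINA6, the corticosteroid-binding globulin, by 2.79 (SE 0.108). The alcohol dehydrogenase ADH6 rose by 2.94, the cadherin CDH16 by 2.76, the phospholipase PLA1A by 2.71, the serine palmitoyltransferase subunit SPTLC3 by 2.65 and the vitamin B12-binding protein TCN1 by 2.57. On log2(TPM + 1) with no filter, which shrinks low levels, the differences were 0.80 for TF, 1.88 for ADH6 and 1.27 for SPTLC3.

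Falls were shallower. The ubiquitin ligase MARCHF4 had a log2 fold change of -1.58 (SE 0.107), from 14.8 ± 1.89 to 4.96 ± 0.357 CPM (n = 3 each). MAP3K14, the kinase of the non-canonical NF-kappaB pathway, had a log2 fold change of -1.49 (SE 0.053) and went from 67.5 to 24.0 CPM. TFPI2, a serine protease inhibitor, was the most abundant of these genes and went from 338 to 158 CPM, a log2 fold change of -1.10 (SE 0.037). SUSD2 stood at -1.15, FBXL16 at -1.16, the GDNF receptor GFRA1 at -1.06, UNC13D at -1.05 and the host transcript MIR193BHG at -1.35. BCYRN1 at -1.18 and the small nucleolar RNA SNORD17 at -1.05 also passed the test, but BCYRN1 has many near-identical copies and its value is uncertain. The counting is not stated to use strand, and MAP3K14, TFPI2, MARCHF4 and FBXL16 overlap genes on the opposite strand.

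**Figure D2:**
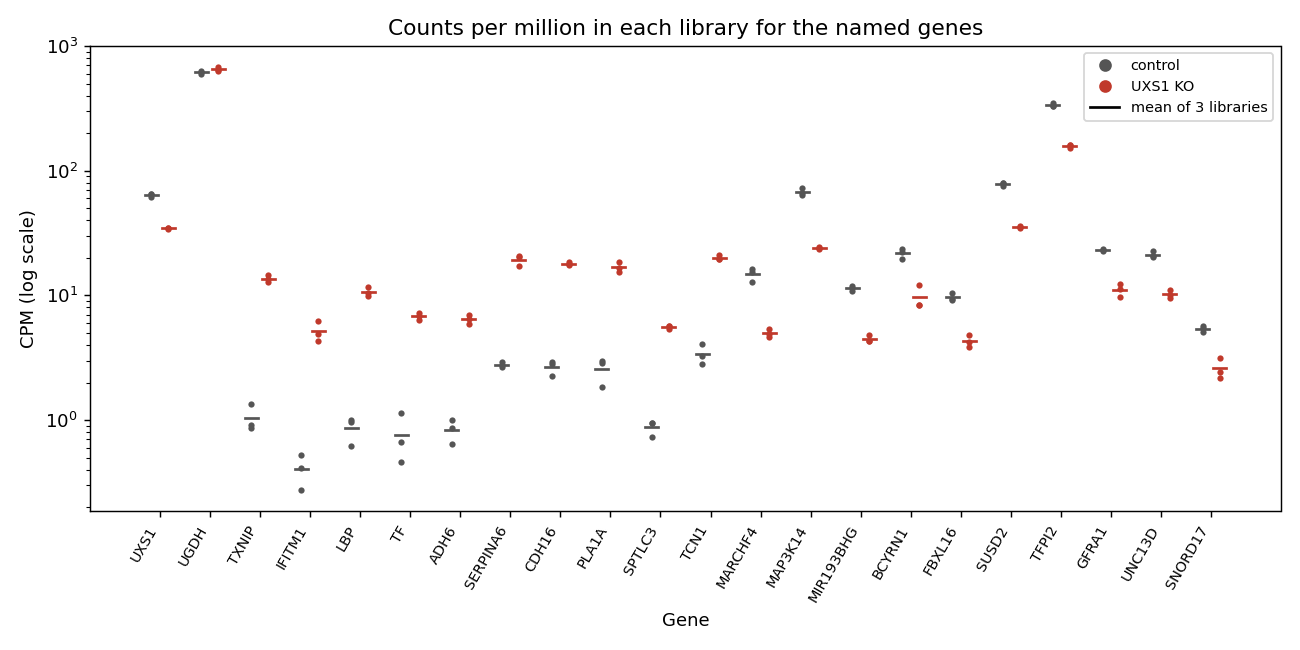
CPM in each of the 6 libraries (log scale) for UXS1, UGDH and the genes with the largest rises and falls; points are single libraries and bars are means of 3 libraries. The UXS1 KO points lie below the control points for UXS1, with means of 34.6 and 63.9 CPM, and above them for TXNIP, with means of 13.6 and 1.03 CPM.

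The fall of division genes took in most members of both lists. For G2/M and mitosis genes the camera adjusted p was 1.4e-26, and it was 0.046 with an estimated correlation. HJURP, a centromere chaperone, had a log2 fold change of -0.91, KIF23 of -0.87, ANLN of -0.82 and the spindle factor TPX2 of -0.78. For G1/S and DNA replication genes the camera adjusted p was 2.3e-22, and adjusted p = 0.057 with an estimated correlation. The ribonucleotide reductase subunit RRM2 stood at -0.93, the helicase subunits MCM5 at -0.90 and MCM7 at -0.71, and thymidine kinase TK1 at -0.81. Adjusted over the list alone, 55 and 51 members were lower. Replication-dependent histone genes did not follow: of 16 tested, 4 rose and 1 fell, with a median of 0.21 (camera adjusted p = 0.18), and adjusted over the list alone 3 rose and 1 fell. H2BC11 had a log2 fold change of -0.80, a call lost with log2(TPM + 1) and no filter, and H3C6 one of 0.44.

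Ribosome biogenesis factors fell in 31 of 39 members and rose in none, with a median of -0.29 (camera adjusted p = 2.6e-10; adjusted p = 0.13 with an estimated correlation); adjusted over the list alone 32 fell. NPM1 stood at -0.48, NCL at -0.47, NOP56 at -0.49 and TCOF1 at -0.46. Cytosolic ribosomal protein genes, of which 29 fell and 8 rose of 78, were not called as a list (camera adjusted p = 0.14), with the same numbers adjusted over the list alone. The list was called lower without CTRL replicate 1 (adjusted p = 0.029) and without CTRL replicate 3 (adjusted p = 0.036). Over the 6 settings with a library left out, its median ran from -0.0739 to 0.0113 and its camera adjusted p reached 0.85.

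The p53 target list was called higher (camera adjusted p = 8.7e-11; adjusted p = 0.046 with an estimated correlation), with 35 of 40 members higher and 1 lower, or 36 and 2 adjusted over the list alone. CDKN1A, a cyclin-dependent kinase inhibitor, rose from 263 ± 11.1 to 505 ± 28.8 CPM (n = 3 each), a log2 fold change of 0.94 (SE 0.041). BTG2 rose by 1.11, ZMAT3 by 0.87 and MDM2, the ubiquitin ligase of p53, by 0.71. Among 36 apoptosis regulators 13 rose and 5 fell, or 14 and 6 adjusted over the list alone, and the list was not called (camera adjusted p = 0.48). Of its members BBC3 rose by 0.72, FAS by 0.54 and TNFRSF10B by 0.42, and BOK had a log2 fold change of -0.66.

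Acute-phase, complement and cytokine receptor genes had the highest median of the lists called, 1.77 (camera adjusted p = 1.2e-11; adjusted p = 0.057 with an estimated correlation), with 17 of 18 higher, also when adjusted over the list alone. Ceruloplasmin (CP) rose from 29.6 ± 1.15 to 147 ± 2.99 CPM (n = 3 each), a log2 fold change of 2.31. Complement C3 rose by 1.76 and fibrinogen FGA by 1.78. The cytokine receptors IL6ST and OSMR, named after their values were seen, rose by 0.37 and 0.41. Interferon-stimulated genes rose in 29 of 35 members and fell in 2, or 30 and 2 adjusted over the list alone, with a median of 0.98 (camera adjusted p = 1.2e-11; adjusted p = 0.13 with an estimated correlation). IFI6 rose by 1.83, from 9.41 to 33.5 CPM, IFITM3 by 0.98 and IFITM2 by 0.83. The last pair is uncertain, since 22.7% of the exonic length of IFITM2 overlaps IFITM1 and 21.3% of that of IFITM3 overlaps a gene on the opposite strand. IFI44L had 63 counts over the UXS1 KO libraries and none over the control libraries, at least 20.98-fold higher against a floor of 3 counts over the group, and the list's median with this bound was also 0.98. NF-kappaB targets and cytokines rose in 17 of 24 members and fell in 1, also when adjusted over the list alone, with a median of 0.40 (camera adjusted p = 1.1e-04; adjusted p = 0.17 with an estimated correlation). PTGS2, the inducible prostaglandin synthase, rose by 0.93, the chemokine CXCL5 by 0.88 and BCL3 by 0.65, while NFKB2 had a log2 fold change of -0.49.

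Of 7 leukocyte markers tested 5 rose and 1 fell, also when adjusted over the list alone, with a median of 1.30 (camera adjusted p = 0.011; adjusted p = 0.13 with an estimated correlation). CD14 rose from 9.15 ± 1.20 to 22.6 ± 0.410 CPM (n = 3 each), while CD79A went from 0.710 to 2.66 CPM, LYZ from 0.0922 to 0.799 CPM and LCP1 from 0.588 to 1.46 CPM. The value of LYZ is uncertain, with 34.0% of its exonic length overlapping a gene on the opposite strand. CORO1A, named after its value was seen, had a log2 fold change of -1.51. Of 8 fibroblast markers 5 rose and 2 fell, also when adjusted over the list alone, with a median of 0.76 (camera adjusted p = 0.39), which was 0.0493 on log2(TPM + 1), and THY1 rose by 0.53 while FBLN1 stood at -0.32 and TWIST2 at -0.45. Only 3 endothelial markers were tested, too few for a list test; 1 of them, EGFL7, rose by 0.24, the median of the 3 was -0.22, and the count adjusted over the list alone was also 1.

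**Figure D3:**
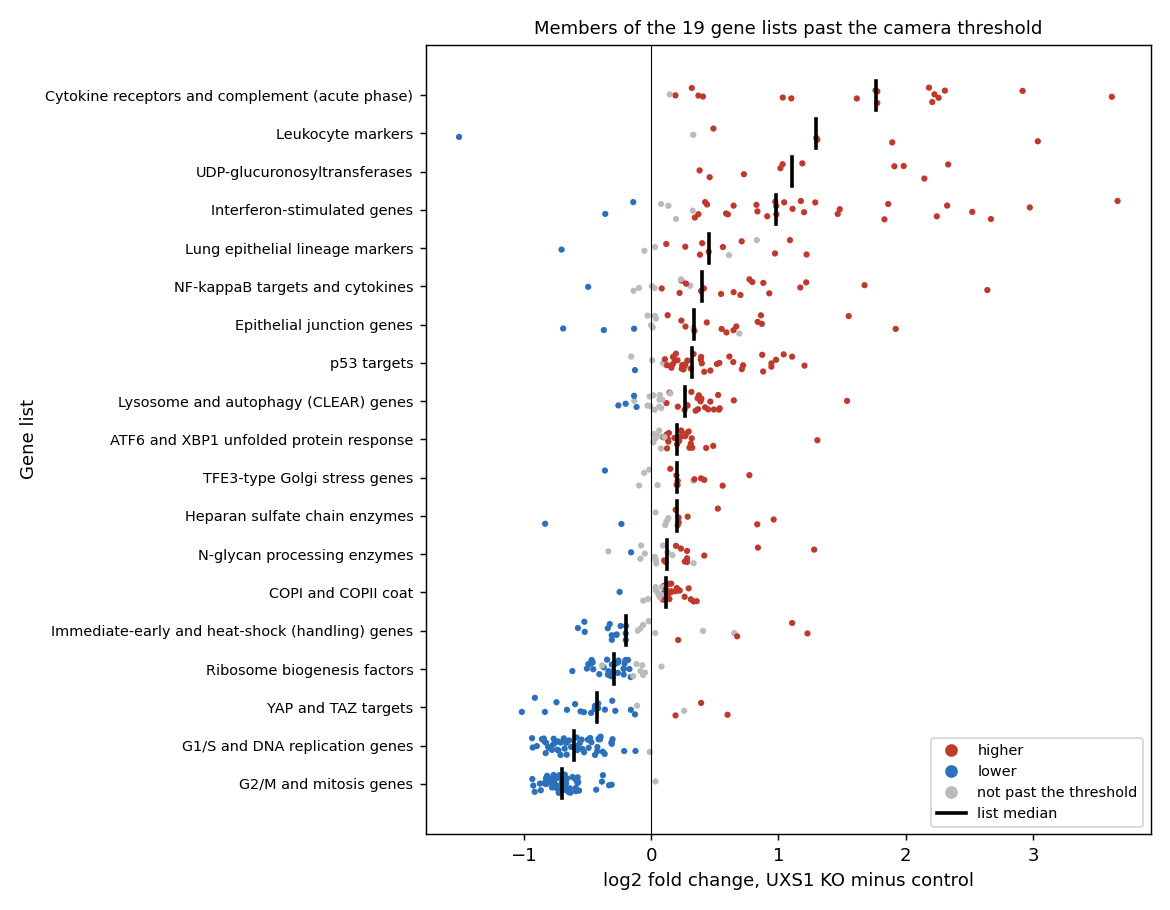
The log2 fold change, UXS1 KO minus control (x axis), of the members of the 19 gene lists past the camera threshold, 1 row per list; red and blue points passed the edgeR threshold, grey points did not, and black bars are list medians. Medians run from 1.77 for acute-phase, complement and cytokine receptor genes to -0.70 for G2/M and mitosis genes; IFI44L, with no control counts, is left out.

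Unfolded protein response genes of the ATF6 and XBP1 branches rose in 24 of 31 members and fell in none, also when adjusted over the list alone, with a median of 0.20 (camera adjusted p = 2.6e-06; adjusted p = 0.17 with an estimated correlation). XBP1, a transcription factor of this response, rose from 85.8 ± 1.76 to 212 ± 4.78 CPM (n = 3 each), a log2 fold change of 1.31, and DNAJB9 rose by 0.49, SEL1L by 0.32 and SYVN1 by 0.31. COPI and COPII coat genes rose in 22 of 34 members and fell in 1, or 23 and 1 adjusted over the list alone, with a median of 0.12 (camera adjusted p = 4.4e-04; adjusted p = 0.13 with an estimated correlation). TMED9 rose by 0.31, TMED10 by 0.29 and SEC24D by 0.33. N-glycan processing enzymes rose in 11 of 24 members and fell in 1, also when adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.13 with an estimated correlation). The sialyltransferase ST6GAL1 rose from 14.9 ± 0.609 to 36.2 ± 1.45 CPM (n = 3 each), and the fucosyltransferase FUT8 rose by 0.42. The list of Golgi stress genes of the TFE3 type rose in 10 of 16 members and fell in 1, also when adjusted over the list alone. Its camera adjusted p was 0.020, and 0.17 with an estimated correlation. ST3GAL1 rose by 0.42 and STX3 by 0.34. HES1, which rose by 0.77, and SERPINH1, by 0.39, were also on the list but are not particular to this response. Lysosome and autophagy genes rose in 23 of 39 members and fell in 4, or 23 and 5 adjusted over the list alone, with a median of 0.26 (camera adjusted p = 4.6e-05; adjusted p = 0.13 with an estimated correlation). GPNMB rose by 1.54, and the lysosomal enzymes TPP1 by 0.54 and GLB1 by 0.53.

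Among the pathways next to UXS1, the enzymes that build on UDP-xylose showed no common direction. Of 15 UDP-xylose and glycosaminoglycan linker enzymes 5 rose and 2 fell, also when adjusted over the list alone; their median was 0.07 and their mean -0.00084, of opposite sign, the test pointed up, and the list was not called (camera adjusted p = 0.51), with medians from 0.0224 without UXS1_KO replicate 3 to 0.104 without CTRL replicate 1. B4GALT7, a linker galactosyltransferase, rose by 0.33, while GXYLT2 stood at -0.90 with a level of 1.22 against 2.29 CPM, and at -0.55 on log2(TPM + 1). Of 33 UDP-sugar and amino-sugar enzymes 11 rose and 7 fell, or 12 and 7 adjusted over the list alone (camera adjusted p = 0.51). UXS1 itself is among the 7 that fell, and UGP2, which makes UDP-glucose, rose by 0.34. Heparan sulfate chain enzymes rose in 8 of 14 members and fell in 2, also when adjusted over the list alone (camera adjusted p = 0.029; adjusted p = 0.16 with an estimated correlation). The sulfatase SULF2 rose by 0.83, HS3ST3B1 by 0.96 and HS2ST1 by 0.29, and NDST1 stood at -0.23. Chondroitin and dermatan sulfate enzymes rose in 6 of 15 members and fell in 2, also when adjusted over the list alone (camera adjusted p = 0.46), and CHPF rose by 0.85. Proteoglycan core genes rose in 15 of 27 and fell in 3, also when adjusted over the list alone (camera adjusted p = 0.059); CD44 rose by 0.36 and GPC1 stood at -0.39, and the list was called higher without UXS1_KO replicate 2 (adjusted p = 0.0418), with a mean CPM of at least 5 (0.0408) and with log2(TPM + 1) (0.0246). SMC3, a cohesin subunit on this list, stood at -0.56. Nucleotide-sugar transporters rose in 8 of 18 and fell in none, also when adjusted over the list alone (camera adjusted p = 0.059), and golgins rose in 10 of 22 and fell in 3, also when adjusted over the list alone (camera adjusted p = 0.059). SLC35D1 rose by 0.38 and GOLM1 by 0.50. With a mean CPM of at least 5 the transporters (adjusted p = 0.0408) and the golgins (0.0384) were called higher, the golgins also with log2(TPM + 1) (0.0450) and with the GC and length correction (0.0318). Hyaluronan genes rose in 2 of 10 and fell in 4, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.60), with HMMR at -0.59.

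Of 24 listed UDP-glucuronosyltransferases, which use UDP-glucuronic acid, only 10 were tested. All 10 tested members rose, also when adjusted over the list alone, with a median of 1.11 (camera adjusted p = 1.7e-04, and 0.13 with an estimated correlation). Their levels were low: UGT2B15 went from 0.758 to 3.01 CPM and UGT2A3 from 0.262 to 1.00 CPM. UGT2A3, UGT2B10 and UGT2B11 passed the minimum count only through the UXS1 KO libraries, so the filter itself favoured rises among them. On log2(TPM + 1) the median of the list was 0.37. Members of this family are near-identical or share exons, so the values of single members are uncertain.

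Targets of YAP and TAZ fell in 19 of 24 members and rose in 3, also when adjusted over the list alone, with a median of -0.42 (camera adjusted p = 9.2e-06; adjusted p = 0.13 with an estimated correlation). ANKRD1 stood at -1.02, AMOTL2 at -0.83, the receptor kinase AXL at -0.74 and MYOF at -0.66. Epithelial junction genes rose in 14 of 24 members and fell in 3, also when adjusted over the list alone, with a median of 0.34 (camera adjusted p = 0.0039; adjusted p = 0.13 with an estimated correlation). The claudin CLDN2 rose from 171 ± 13.1 to 501 ± 32.5 CPM (n = 3 each) and E-cadherin (CDH1) by 0.86, while KRT7 stood at -0.69. Lung epithelial lineage markers rose in 10 of 15 members and fell in 1, also when adjusted over the list alone, with a median of 0.45 (camera adjusted p = 0.011; adjusted p = 0.13 with an estimated correlation). The mucins MUC5B, MUC1 and MUC5AC rose by 1.22, 1.09 and 0.97, and CAV1 stood at -0.70. TGF-beta response and mesenchymal genes rose in 6 of 35 members and fell in 18, or 8 and 18 adjusted over the list alone (camera adjusted p = 0.093; 0.0408, called lower, with a mean CPM of at least 5), with FN1 up by 0.82. Collagen and basement membrane genes rose in 12 of 29 and fell in 5, also when adjusted over the list alone (camera adjusted p = 0.075), and COL4A5 rose by 0.74. Immediate-early and heat-shock genes, which respond to handling, fell in 13 of 24 and rose in 4, or 14 and 5 adjusted over the list alone (camera adjusted p = 0.043; adjusted p = 0.38 with an estimated correlation). DUSP1 and KLF6 each stood at -0.52 and ZFP36 rose by 0.68; the call was lost with the replicate block (adjusted p = 0.056), without UXS1_KO replicate 2 (0.051), without UXS1_KO replicate 3 (0.12), without CTRL replicate 2 (0.13) and without CTRL replicate 3 (0.068).

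The remaining lists were not called. Integrated stress response genes rose in 7 of 34 and fell in 17, or 9 and 17 adjusted over the list alone (camera adjusted p = 0.11); the amino acid transporter SLC7A5 stood at -0.49 and SESN2 rose by 0.88. NRF2 targets rose in 16 of 41 and fell in 10, or 18 and 11 adjusted over the list alone (camera adjusted p = 0.46), with GPX2 up by 1.04 and HMOX1 at -0.82. Glycolysis genes rose in 4 of 24 and fell in 11, or 4 and 12 adjusted over the list alone (camera adjusted p = 0.10), with PFKP at -0.57 and ALDOC up by 1.24. Hypoxia genes rose in 12 of 30 and fell in 9, also when adjusted over the list alone (camera adjusted p = 0.51), with CA12 up by 0.81 and ADM at -0.67. Outputs of the MAPK pathway rose in 9 of 25 and fell in 6, also when adjusted over the list alone (camera adjusted p = 0.57), with MYC at -0.62. Receptor tyrosine kinases rose in 8 of 26 and fell in 7, or 9 and 8 adjusted over the list alone (camera adjusted p = 0.99, median -0.04, mean 0.04, test pointing down), and ERBB3 rose by 1.55 and FGFR4 by 0.89. Cholesterol synthesis genes rose in 10 of 25 and fell in 4 (camera adjusted p = 0.21) and fatty acid synthesis genes rose in 13 of 23 and fell in 2 (camera adjusted p = 0.15), in both also when adjusted over the list alone; ACSS2, on the fatty acid list, rose by 0.36. Nuclear-encoded respiratory chain genes rose in 12 of 53 and fell in 9, also when adjusted over the list alone (camera adjusted p = 0.82), with UQCRC2 up by 0.24. Mitochondrial-genome transcripts rose in 2 of 15 and fell in 2, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.99, median -0.0012, mean 0.012, test pointing up), with MT-RNR1 at -0.28, and took 3.29% to 3.79% of counts in the 6 libraries.

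Of 42 lists tested with camera at a preset correlation, 14 were higher and 5 lower; with an estimated correlation 1 was higher, the p53 targets, and 1 lower, the G2/M and mitosis genes. The first principal component held 69.4% of the variance and parted the groups, and 54.5% of tested genes had groups that did not overlap, where chance gives 10%. Exonic overlap with other genes also makes the values of RRM2 (20.2%), CP (19.4%), TPP1 (14.4%) and FUT8 (12.3%) uncertain.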

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

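The GC and length correction was chosen after seeing the data; the other alternatives were not. Numbers of genes higher (3863) and lower (3727) stayed within 1.5 times under all 19 alternatives, from 2855 to 4243 higher and 2661 to 3896 lower, and no gene called by edgeR and by an alternative had opposite signs. UXS1 kept its call, with log2 fold changes from -0.92 to -0.85. Genes at least 2-fold lower numbered 175 with no filter. With a mean CPM of at least 5 there were 162 higher and 11 lower by 2-fold, with log2(TPM + 1) 233 and 46, and with log2(TPM + 1) and no filter 231 and 37; the CPM minimum removes genes with low counts and the pseudocount shrinks low values. Lists called numbered 1 higher and 1 lower with an estimated correlation, and 28 and 8 with fry, which does not compare a list with other genes. Of the named genes none reversed and 10 lost the call under some alternative, UGDH among them. List medians here are differences of mean log2 CPM or log2(TPM + 1). The direction of the test turned for 4 lists, none past the threshold. Receptor tyrosine kinases turned with fry (median -0.0353), with log2(TPM + 1) (-0.0355) and with some libraries left out (-0.0565 to 0.0221 over the 6). Mitochondrial-genome transcripts turned with fry (-0.0057) and with some libraries left out (-0.0384 to 0.0749), nuclear-encoded respiratory chain genes with some libraries left out (-0.0167 to 0.0570), and fibroblast markers with log2(TPM + 1) (0.0493). The cause was not tested.

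The replicate block gave 4002 genes higher and 3896 lower, and 593 and 85 by 2-fold; it called 14 lists higher and 4 lower, with no change to a call but that of the immediate-early list. Replicate numbers pair the libraries weakly if at all. Same-numbered libraries had deviations correlated at 0.0055 to 0.034, and 5 of 6 libraries correlated best with their own number. No label says what the numbers mark, so a weak pairing is not excluded. Depth limits genes under 1 CPM, which stands for 21.1 counts in the shallowest library.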

Other observations

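The tests of scaling and of genes near the count floor were chosen after the results were seen, as were the added gene lists and the GC and length correction. Lists added after the top genes were seen were tested without the genes already named and without genes of the other lists. Their camera p values were adjusted over the 6 added lists alone, and those of the fixed lists over 42. Adjusted p values of added and fixed lists are therefore not directly comparable. Liver-type plasma protein genes rose in 20 of 25 members and fell in none, with a median log2 fold change of 1.56 (camera adjusted p = 1.4e-09; adjusted p = 0.013 with an estimated correlation). Transthyretin (TTR) rose by 3.94, complement factor CFI by 3.08, angiotensinogen (AGT) by 2.44 and retinol-binding protein RBP4 by 1.64, while vitronectin (VTN), with a mean of 67.1 CPM over the 6 libraries, rose by 0.97; TTR, CFI and AGT lay at 2.07, 1.69 and 2.99 CPM. MHC class I antigen presentation genes rose in 13 of 15 members and fell in none, with a median of 0.54 (camera adjusted p = 1.6e-06; adjusted p = 0.018 with an estimated correlation), among them B2M by 0.62, HLA-B by 0.73 and TAPBP by 0.54; reads shared between HLA genes make their single values uncertain. Values fit the hypotheses that these groups rose with the acute-phase, complement and interferon-stimulated genes, found and tested on the same data.

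CTPS1, which makes CTP, had a log2 fold change of -1.02. The hypothesis that nucleotide synthesis genes fell with it was tested on 2 lists. Of 14 pyrimidine genes 9 fell and 2 rose (median -0.19, camera adjusted p = 0.026, and 0.27 with an estimated correlation). Of 15 purine genes 12 fell and 2 rose (median -0.22, camera adjusted p = 5.7e-04, and 0.054 with an estimated correlation). The G1/S (median -0.61) and ribosome biogenesis (median -0.29) lists fell too, so these falls do not single out a link with CTPS1. Actin cytoskeleton and SRF target genes fell in 19 of 27 members and rose in 2 (median -0.17, camera adjusted p = 1.3e-04; adjusted p = 0.095 with an estimated correlation), with tubulins TUBB6 at -0.65 and TUBA1A at -0.12 among them, FLNA at -0.48 and ACTN4 at -0.51. Of 10 glucose-responsive MondoA genes other than TXNIP, 5 rose and 2 fell (median 0.21, camera adjusted p = 0.078; adjusted p = 0.27 with an estimated correlation), and ARRDC4 rose by 1.52; the test leaves open whether they rose with TXNIP.

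With 3 against 3 libraries there are 10 splits, 1 of which gave as many genes as the real one, itself; these are too few for a share under 0.05. The real split called 7590 genes and the highest other split 0 with edgeR and 0 with limma-voom. At an unadjusted p under 0.05 the highest other split had 245 genes with edgeR. Every other split mixes libraries of both groups, so the group difference adds to its spread and few calls follow in any case. The contrast with the real split therefore decides nothing about chance.

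The p53 target list rose. A trend with GC content and transcript length is argued against as the whole cause: the list's median was 0.32 before and 0.32 after correction, and the list stayed called (camera adjusted p = 6.5e-11). Double-strand breaks made by the targeting guide may contribute, since the non-targeting guide makes none. All 5 of CDKN1A, MDM2, FDXR, ZMAT3 and SPATA18, chosen before their values were seen, were higher. They are p53 targets, so any origin of a p53 response could raise them, and their rise does not single out breaks. Loss of UXS1 itself is open too and untested, because no control guide that cuts elsewhere is among the groups. The UXS1 KO libraries share a single guide, so other effects of that guide cannot be told apart from loss of UXS1 either.

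The division cycle lists fell. A trend with GC content and length is argued against: after correction the medians were -0.60 for G1/S and -0.68 for G2/M genes. Fewer cycling cells could give medians such as -0.70 for G2/M genes, but the replication-dependent histones, with a median of 0.21, did not follow. Their transcripts lack a poly(A) tail and the selection of messenger RNA is not given, so this cannot be told apart from a fall of these transcripts in cells that still cycle. Loss of UXS1 and the p53 response are both open as untested origins.

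Rises of at least 2-fold outnumbered falls. Scaling stays open: the ratio of rises to falls was at least 6.96 over 4 scalings, but these moved the median log2 fold change of all tested genes by too little to decide, to at most 0.02. The excess of rises was not confined to genes near the count floor: among genes with at least 5 CPM 157 rose and 12 fell, a ratio of 13.1. Most of the 592 rises and 84 falls over all tested genes did lie under that level. Genomic DNA in the UXS1 KO libraries is argued against by the summed counts of 48 olfactory receptor genes, whose ratio was 1.11 (95% exact binomial interval 0.979 to 1.26, counting error only). Unspliced RNA was not tested. Cells of another type were not tested directly, and only 7 of 20 listed leukocyte markers passed the filter. Of these 5 were higher and 1, CORO1A at -1.51, was lower (median 1.30, camera adjusted p = 0.011, and 0.13 with an estimated correlation). Fibroblast markers were not called. These mixed values leave cells of another type open, and a response of the cells to the UXS1 guide remains a hypothesis.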
